A study of Musca domestica with 10 samples.

How the data were processed

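RNA from whole house fly embryos was measured at 5 stages with 2 biological replicates of 100 embryos per stage, and the stage and replicate number of each of the 10 libraries were taken from the labels. Per the labels' protocols, embryos were frozen, RNA was extracted with Tri-reagent and treated with DNase, and libraries with an insert of 200 bp were sequenced on a HiSeq2000 as paired reads of 100 bp. The deposited files hold raw counts of reads per gene, 1 file per library, and the values are whole numbers that sum to different totals. The submitters' processing notes name STAR and HTSeq, without versions. The genome build, the annotation, the strand setting and any read filters are not given in the sources used here. Reads ambiguous between genes, or aligned to more than 1 place, were set aside from the gene counts. Whether the counts of overlapping genes, antisense genes and near-identical copies are complete, or carry reads of a neighbour, therefore cannot be told here.

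Each file lists 15803 genes and 5 rows that name no gene, which were kept out of library sizes and tests. Of all reads in these files, 10.5% to 25% were assigned to no gene, 5.31% to 10.7% aligned to more than 1 place and 0.353% to 0.661% were ambiguous between genes. Reads assigned to genes numbered 16288442 in syncytial blastoderm replicate 1 and 42479342 to 83604709 in the others. On TMM-scaled library sizes, a count of 3 corresponded to 0.14 CPM in the shallowest library and to 0.036 to 0.077 CPM in the others, so levels below this rest on few reads. The 10 most abundant genes took 6.63% to 13.8% of a library's gene reads, and TMM factors ran from 0.793 to 1.36. No pair of libraries agreed within sampling noise (the lowest chi-square per degree of freedom was 191, between gastrula replicate 1 and germ band extension replicate 1), so each was kept as its own sample.

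The tests were fitted in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by stage at its default settings, which left 11286, and libraries were scaled by TMM. A quasi-likelihood model with robust dispersions and 1 coefficient per stage was fitted to all 10 libraries, which share 1 estimate of the spread on 5 residual degrees of freedom. It was tested for 4 adjacent steps, for dorsal closure against syncytial blastoderm, and over all stages. Calls are at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold change. Log2 fold changes are the fitted ones with edgeR's prior count, and standard errors are the unshrunken change divided by the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM for components and correlations adds a prior count of 2. The peak stage of a gene is the stage of its highest mean log2 CPM among genes called over all stages.

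These designs, the alternatives and the rule for named identifiers were fixed before the data were examined. The alternatives were 3 other scalings (DESeq2 size factors, total counts, upper quartile), no filter beyond 1 count in total, a stricter filter (CPM of at least 5 in at least 2 libraries), DESeq2 1.42.0 and limma-voom (limma 3.58.1). The others were a block for the replicate number, only the libraries of the 2 stages compared, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Where this leaves 1 library in a stage, that library is assumed to vary like the other stages. The rule for identifiers took, per adjacent step, the 2 largest rises and the 2 largest falls among called genes with a mean of at least 20 CPM in the higher stage, at least 10 counts in the lower stage and the same direction in all pairs of libraries. For the step from cellular blastoderm to gastrula, which had no calls without the block, it was applied to the blocked test after the data were seen. Groups by onset, loss and constancy were also defined after the data were seen.

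Gene lists had been fixed for developmental regulators and cell functions, but 0 of the 15803 identifiers matched the reference gene table, which is of another annotation, so no list was tested and no name is given.

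The labels give the replicate numbers 1 and 2 in every stage but do not say that a number marks a shared batch. Replicate 2 minus replicate 1 differences in log2 CPM correlated across genes between stages in all 10 pairs of stages, at r from 0.32 to 0.61, above the 0.1 set as the level for pairing. The numbers were therefore treated as pairing the samples, and the blocked result (4 residual degrees of freedom) is given beside the counts of calls and the tests of named identifiers. The common biological coefficient of variation was 0.69 without the block and 0.46 with it.

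The edgeR steps were tested on simulated data for cellular against syncytial blastoderm, with 200 genes changed. These were drawn from genes with a mean CPM of at least 5, so recovery of genes at lower levels was not tested. Counts were drawn from each gene's mean over all libraries, the real library sizes and fitted dispersions. Without a simulated replicate effect the dispersions came from the fit without the block, which takes the replicate difference up as spread. With the effect they came from the blocked fit, so the 2 settings differ in noise as well. Unlike in the data, all other genes had the same mean at every stage. Recovery under adjustment depends on how many genes change, so these counts do not give the recovery in the data. With changes of up to 16-fold and no replicate effect, 0 of the 200 were recovered among 11011 genes, with or without the block. The simulated replicate effect was each gene's fitted difference, limited to 5 on the log2 scale and the same at every stage. In the data the differences correlated between stages at r from 0.32 to 0.61. With this effect, 0 were recovered without the block and 100 with it among 11156 genes. The 100 were 2, 18, 37 and 43 of the 50 changed 2-, 4-, 8- and 16-fold, with 6 false calls. A set with changes of up to 256-fold, added after this was seen, gave 27, 35 and 37 of the 40 genes changed 16-, 64- and 256-fold without the block or a replicate effect (11085 genes; 23, 33 and 37 with the block), and 17, 24 and 30 without the block under a replicate effect (11132 genes; 37, 38 and 39 with the block). Without the block, median estimates for those 16-fold genes were 4.12 and 4.04 on the log2 scale, against the 4 simulated. In the same fit, 0.97% of the unchanged genes had an unadjusted p under 0.05 under a replicate effect, so that test was conservative there.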

Results

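Messenger RNA was profiled in whole embryos of the house fly at 5 successive stages. The first was the syncytial blastoderm, in which the nuclei share a common cytoplasm, followed by the cellular blastoderm, in which membranes enclose them. The later ones were the gastrula, when the germ layers form, germ band extension, when the trunk lengthens, and finally dorsal closure, when the epidermis closes over the back. Each stage was represented by 2 biological replicates of 100 embryos, giving 10 libraries. Reads assigned to genes ranged from 16288442 in syncytial blastoderm replicate 1 to 83604709 in cellular blastoderm replicate 1. The remaining libraries held between 42479342 and 81097276. Between 7110 and 9728 of the 15803 annotated genes reached 1 CPM (reads of the gene relative to the scaled library size) in a library, with the most in the dorsal closure libraries (9728 and 9249). The count files identify genes by MDOA identifiers and do not pair them with gene names, so genes are described below by identifier and by their course over the stages.

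The libraries lay in the order of development. On the first principal component, which held 59.4% of the variance of log2 CPM, scores ran from -161.6 and -140.7 at syncytial blastoderm to 290.6 and 274.3 at dorsal closure. The second component (19.7%) set the gastrula and germ band extension libraries (93.4 to 98.1) apart from syncytial blastoderm (-134.4 and -127.7) and dorsal closure (-81.6 and -43.4). The third component (10%) separated the replicate numbers: all 5 replicate 1 libraries had positive scores and all 5 replicate 2 libraries negative ones. The germ band extension libraries were further apart on the first component (-16.9 and 69.2) than those of any other stage. Across all tested genes, however, the dorsal closure libraries correlated least of the same-stage pairs (r = 0.85, against 0.895 at germ band extension).

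**Figure D1:**
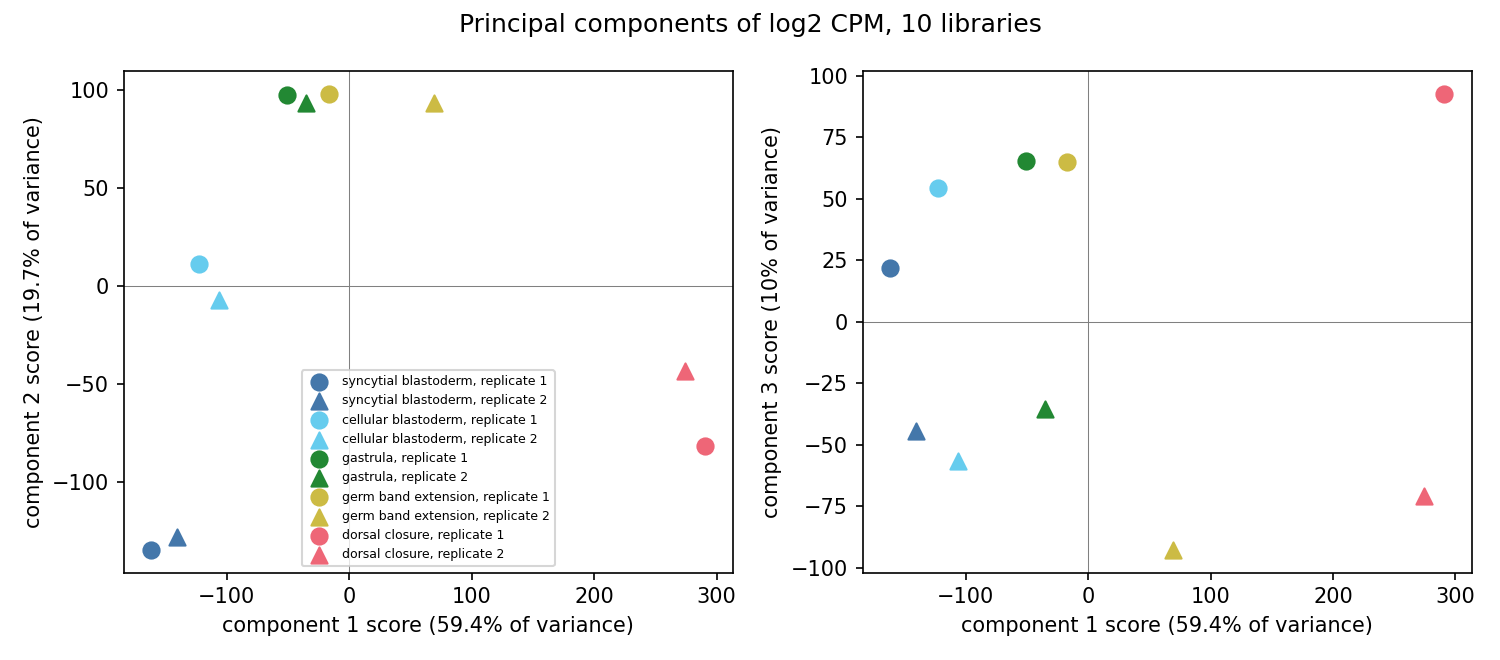
Scores of the 10 libraries on principal components 1 and 2 (left) and 1 and 3 (right), computed from log2 CPM, with colour for the stage and symbol for the replicate number. Component 1 places dorsal closure (290.6 and 274.3) far from the other stages, and component 3 parts replicate 1 (circles, above 0) from replicate 2 (triangles, below 0).

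Expression of 4563 of the 11286 tested genes (40.4%) differed between any of the 5 stages. Most of these genes had their highest mean at the ends of the series: 2522 (55.3%) at dorsal closure and 907 (19.9%) at syncytial blastoderm. Fewer were highest at gastrula (478), cellular blastoderm (338) or germ band extension (318). The highest stage was the same in both replicate series for 3800 of the 4563 genes (83.3%). The test that chose these genes favours those whose replicates agree, so this share is not an independent measure of agreement. The test was edgeR's quasi-likelihood F test over all stages at a Benjamini-Hochberg adjusted p under 0.05. With the replicate number as a block it called 7590 genes (67.3%), of which 1820, 820, 1215, 570 and 3165 were highest at the successive stages. Dorsal closure replicate 1 weighed most: without it 2861 genes were called, and 1422 of them were highest at dorsal closure.

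The peak counts of the earlier stages moved with single libraries. Leaving out any library also lowered the number of genes called over all stages, so a drop need not be particular to the library left out. The syncytial blastoderm count was 548 and 468 without syncytial blastoderm replicate 1 and 2, and 602 without gastrula replicate 2. For cellular blastoderm it was 209 without syncytial blastoderm replicate 1, 221 and 206 without gastrula replicate 1 and 2, and 183 and 197 without dorsal closure replicate 1 and 2. For gastrula it was 262 and 253 without syncytial blastoderm replicate 1 and 2, 295 without cellular blastoderm replicate 2, and 286 and 257 without gastrula replicate 1 and 2. It was 299 and 176 without germ band extension replicate 1 and 2, and 218 and 178 without dorsal closure replicate 1 and 2. For germ band extension it was 200 and 195 without syncytial blastoderm replicate 1 and 2, and 208 without gastrula replicate 2. Scaling to total counts alone gave 1453 genes highest at syncytial blastoderm and 254 highest at gastrula.

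Genes that were silent or nearly so at the start and then switched on formed a large group. Below 1 CPM in both syncytial blastoderm libraries, 1110 genes later reached 10 CPM in both libraries of a stage. These floors were chosen after the data were seen. Of the 1110, 119 first did so at cellular blastoderm, 172 at gastrula, 87 at germ band extension and 732 at dorsal closure. Without one of the germ band extension libraries these onsets shifted: 330 genes first reached the floor at germ band extension without replicate 1, and 129 without replicate 2 (the lone library then stands for the stage). Without dorsal closure replicate 2 the dorsal closure onsets numbered 1184.

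The median level of the 119 genes first high at cellular blastoderm was 0.135 and 0.0811 CPM in the syncytial blastoderm libraries and 54.3 and 31.8 CPM at cellular blastoderm. It was 71.3 and 76.4 CPM at gastrula and 18.9 and 24.1 CPM at dorsal closure. The 732 genes first high at dorsal closure took 0.0096% and 0.0104% of the gene reads at syncytial blastoderm and 12.6% and 6.76% at dorsal closure. In germ band extension their share was 0.102% in replicate 1 and 0.537% in replicate 2. A set of 27 transient genes was below 1 CPM at both ends of the series and at or above 10 CPM in both libraries of a middle stage. Of these 27, 22 were high at cellular blastoderm, 14 at gastrula and 5 at germ band extension.

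Genes that were lost formed a smaller group, under a narrower rule. Onset counted at any later stage, but loss was judged at dorsal closure alone, so the sizes of the groups do not compare rises with falls. At or above 10 CPM in both syncytial blastoderm libraries and below 1 CPM in both dorsal closure libraries were 53 genes. Their median level went from 44.3 and 53.4 CPM at syncytial blastoderm to 10.8 and 15.3 CPM at cellular blastoderm and 3.64 and 2.41 CPM at gastrula. The number was 140 without dorsal closure replicate 1 and 80 without dorsal closure replicate 2. In contrast, 3710 genes stood at or above 10 CPM in all 10 libraries, and together they held 72.3% to 90.8% of the gene reads of each library. Of these 3710, 800 still differed between stages, and 2330 did with the replicate block.

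From syncytial to cellular blastoderm, the step at which membranes enclose the nuclei, 259 genes rose and 51 fell. The called genes that rose had a median log2 fold change of 7.78, against -2.9 for those that fell. For genes that start with few reads, the size of the rise depends on the prior count. The 119 genes first high at cellular blastoderm had medians of 0.135 and 0.0811 CPM at syncytial blastoderm. There, 3 counts correspond to 0.14 and 0.061 CPM. MDOA000456 rose from 0.333 ± 0.357 to 485 ± 359 CPM (SD, n = 2), a log2 fold change of 10.62 ± 1.51 (SE, edgeR adjusted p = 0.008), and stood at 29.9 ± 17.3 CPM at gastrula, still above its starting level. MDOA001171 rose from 1.17 ± 1.34 to 1510 ± 950 CPM, a log2 fold change of 10.38 ± 1.44 (edgeR adjusted p = 0.0073), and stood at 58.3 ± 6.15 CPM at gastrula. MDOA006552 fell from 22.5 ± 8.9 to 0.215 ± 0.207 CPM, with a log2 fold change of -6.66 ± 1.23 (edgeR adjusted p = 0.026). MDOA008702 fell from 75 ± 5.58 to 1.29 ± 0.0546 CPM, with a log2 fold change of -5.86 ± 1.11 (edgeR adjusted p = 0.029), and was at 38.7 and 4.88 CPM in the dorsal closure libraries. In edgeR with the replicate block, the adjusted p of these genes was, in the order given, 4.4e-05, 0.0012, 0.0061 and 0.0065. Across the 11286 genes, called or not, 68.6% changed in the same direction in both replicate series, and the log2 fold changes of the series correlated at r = 0.704 (genes are not independent replicates).

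The number of calls at this step depended on the model and the libraries. With the replicate block 494 genes rose and 410 fell, and 54.6% of the calls were rises, against 83.5% without it. Without the block, DESeq2 gave 55.9% (567 higher and 447 lower), limma-voom 70.2% (228 and 97) and edgeR on only the 2 stages 76.1% (118 and 37). Scaling to total counts alone gave 69.3% (226 higher and 100 lower). In some of the fits with the block that were chosen after seeing the data, falls outnumbered rises. Rises were 36.4% of the calls with total counts (428 and 747), 44.2% in limma-voom (531 and 670), and 46.7% and 46.2% without germ band extension replicate 1 and 2. They were 54.5% with DESeq2's size factors and 54.3% in DESeq2. The rises numbered 89 and 75 without syncytial blastoderm replicate 1 and 2, and 165 without cellular blastoderm replicate 1. The falls numbered 1, 0, 0 and 2 without each of the syncytial and cellular blastoderm libraries in turn. They numbered 14 and 15 without gastrula replicate 1 and 2, and 83 and 82 without germ band extension replicate 1 and 2. The adjusted p of MDOA006552 was 0.085, 0.14, 0.064 and 0.12 and that of MDOA008702 was 0.12, 0.14, 0.21 and 0.17 without each of the 4 libraries of these stages in turn. That of MDOA000456 was 0.077 without syncytial blastoderm replicate 2.

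From cellular blastoderm to gastrula, when the germ layers form, 0 genes passed the threshold in either direction in edgeR's quasi-likelihood test, with 1424 genes at an unadjusted p under 0.05. With the replicate block, 437 genes rose and 317 fell. DESeq2 without a block called 560 higher and 342 lower, and limma-voom called 0. Without any filter on low counts edgeR called 57 higher and 17 lower. Without dorsal closure replicate 1 it called 1 gene lower, and without dorsal closure replicate 2 it called 2. The log2 fold changes of the replicate series correlated at r = 0.676 across the genes, and 70.5% of all genes changed in the same direction in both. Rises were 58% of the calls with the block and 48.1% with the block and total counts (401 and 432).

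The identifiers from the blocked test were chosen after its calls were seen. MDOA003793 stood at 0.184 ± 0.226 CPM at cellular blastoderm and 32.5 ± 12.2 CPM at gastrula (SD, n = 2), a log2 fold change of 8.07 ± 1.11 (SE, adjusted p = 0.0058 in edgeR with the block, 0.087 without). MDOA003795 stood at 0.143 ± 0.186 and 28.1 ± 19.4 CPM, a log2 fold change of 7.65 ± 1.2 (adjusted p = 0.012 with the block, 0.084 without). Both had a library with a count near the floor at cellular blastoderm (0.0241 and 0.012 CPM). MDOA000113 was high at cellular blastoderm alone of the 5 stages, at 45.5 ± 7.99 CPM, and stood at 0.342 ± 0.0855 CPM at gastrula. Its log2 fold change was -7.18 ± 0.99 (adjusted p = 0.0054 with the block, 0.075 without). MDOA007880 went from 282 ± 91.2 CPM at syncytial blastoderm to 24.8 ± 20.1 at cellular blastoderm and 0.321 ± 0.198 at gastrula, a log2 fold change at the latter step of -6.15 ± 0.62 (adjusted p = 0.0039 with the block, 0.075 without).

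From gastrula to germ band extension, as the trunk lengthens, 0 genes passed the threshold in edgeR, with or without the replicate block. At an unadjusted p under 0.05 stood 573 genes without the block and 1089 with it. limma-voom called 0, and DESeq2 called 170 higher and 4 lower without the block and 326 genes with it, of which 24 were lower. The replicate series differed in how much changed. In replicate 1, 305 genes differed 4-fold or more between the stages, in replicate 2 it was 1972, and 184 did so in the same direction in both. The log2 fold changes of the series correlated at r = 0.452, the lowest of the 5 comparisons. Placed on a scale from syncytial blastoderm (0) to dorsal closure (1) within its own series, germ band extension replicate 1 stood at 0.382, close to gastrula replicate 1 at 0.319. Replicate 2 stood at 0.576, against 0.354 for gastrula replicate 2. Without germ band extension replicate 1, edgeR called 38 genes higher in germ band extension, and 386 higher and 24 lower with the block. Without germ band extension replicate 2 it called 0 genes, and 1 higher and 0 lower with the block.

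From germ band extension to dorsal closure, when the epidermis closes over the back, 1084 genes rose and 852 fell. The genes that rose had a median log2 fold change of 6.85 and those that fell one of -2.73. MDOA004530 rose from 0.125 ± 0.115 to 770 ± 827 CPM (SD, n = 2), a log2 fold change of 12.49 ± 1.74 (SE, edgeR adjusted p = 0.0067). MDOA006531 rose from 0.682 ± 0.842 to 3510 ± 4560 CPM, a log2 fold change of 12.3 ± 2.46 (edgeR adjusted p = 0.015). In both the dorsal closure libraries were far apart, at 1350 and 186 CPM for MDOA004530 and at 6740 and 291 CPM for MDOA006531. MDOA010623, at 2070 ± 58.4 CPM at gastrula, went from 1280 ± 1070 CPM at germ band extension to 3.06 ± 3.63 CPM at dorsal closure. Its log2 fold change was -8.71 ± 1.39 (edgeR adjusted p = 0.0082). MDOA014697 fell from 54.9 ± 30.9 to 0.193 ± 0.171 CPM, a log2 fold change of -8.21 ± 1.66 (edgeR adjusted p = 0.016). In edgeR with the replicate block, the adjusted p of these genes was, in the order given, 0.00036, 0.0013, 0.0017 and 0.0022. Of all 11286 genes, 84.4% changed in the same direction in both replicate series, whose log2 fold changes correlated at r = 0.871 across the genes.

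With the replicate block the numbers at this step were 2274 higher and 2265 lower. Without it, DESeq2 called 2236 higher and 1187 lower, limma-voom 2202 and 1101, and edgeR on only the 2 stages 421 and 22 (95% rises). Single libraries moved the calls: without dorsal closure replicate 1 edgeR called 182 higher and 91 lower, and without germ band extension replicate 1 it called 259 higher and 141 lower. The falls also dropped to 471 without dorsal closure replicate 2, 431 without gastrula replicate 2 and 564 without syncytial blastoderm replicate 2. DESeq2's size factors moved the share of rises among the calls from 56% to 70.2% (1347 higher and 573 lower) and the median log2 fold change of all genes from 0.011 to 0.388. The adjusted p of MDOA006531 was 0.054 and that of MDOA014697 was 0.089 without dorsal closure replicate 1.

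**Figure D2:**
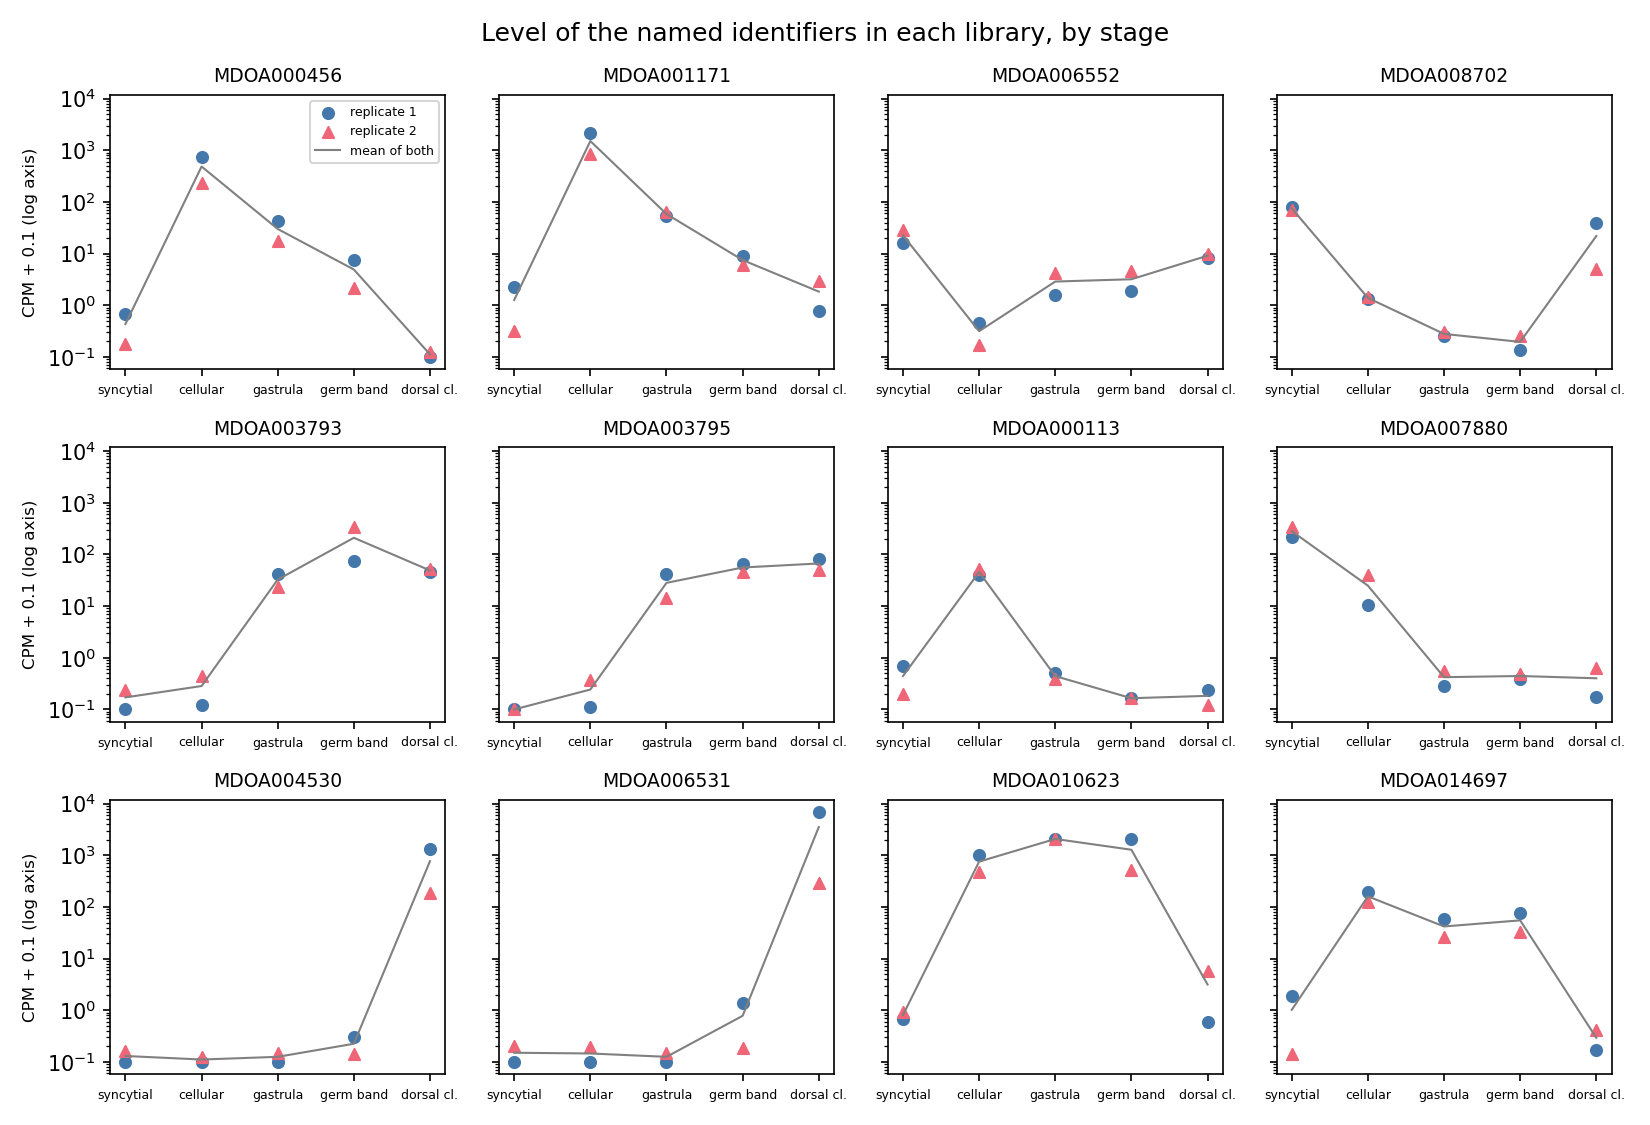
CPM plus 0.1 on a log axis (y) over the 5 stages (x) for 12 identifiers, with a symbol per library and a line through the mean of both replicates. MDOA000456 and MDOA001171 are highest at cellular blastoderm (485 and 1510 CPM), and MDOA004530 and MDOA006531 stand below 1.5 CPM in each library before dorsal closure.

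Over the whole series, from syncytial blastoderm to dorsal closure, 2897 genes rose and 1722 fell. Among these called genes rises were larger than falls, with median log2 fold changes of 8.92 and -2.72, and 2803 of the rises and 1323 of the falls were 4-fold or more. For genes that start with few reads, the size of the rise depends on the prior count. The 732 genes first high at dorsal closure had medians of 0 and 0.0405 CPM in the syncytial blastoderm libraries. The log2 fold changes of the replicate series correlated at r = 0.903 across genes, and 84.5% of all genes changed in the same direction in both. The split between rises and falls moved with the scaling. Rises made up 62.7% of the calls with the main scaling, 75.9% with DESeq2's size factors (3328 higher and 1059 lower), 73% with the upper quartile (3186 and 1176) and 55.3% with total counts alone (2703 and 2189). The median log2 fold change of all genes was 0.148, 0.775, 0.64 and -0.191 under these scalings.

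With the replicate block 3612 genes rose and 3103 fell over the whole series (53.8% rises), and 3246 of the rises and 1798 of the falls were 4-fold or more. With the block and total counts, a pair of choices added after seeing the data, falls outnumbered rises (3360 rises and 3806 falls, 46.9% rises). Without syncytial blastoderm replicate 1 the numbers were 1186 and 877, and without replicate 2 they were 1095 and 763. Without dorsal closure replicate 1 there were 1902 rises, and without dorsal closure replicate 2 there were 947 falls.

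**Figure D3:**
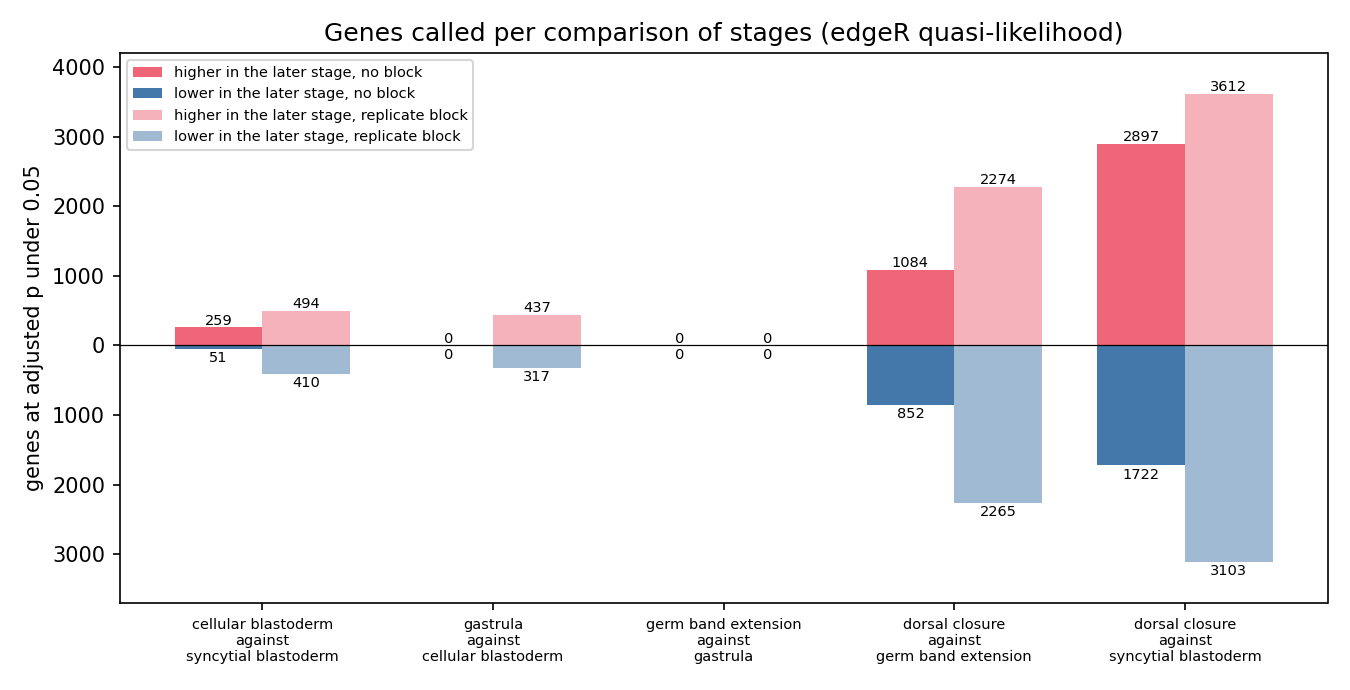
Number of genes called at an adjusted p under 0.05 (y axis) for the 5 comparisons of stages (x axis), with rises above 0 and falls below 0, without (solid) and with (pale) the replicate block. The step from germ band extension to dorsal closure has the most calls of the adjacent steps (1084 rises and 852 falls without the block), and the step from gastrula to germ band extension has 0 in both tests.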

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

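The tests on sequencing depth, on developmental age, on library batch and on mixed embryos were chosen after the results they measure had been seen, and the splits of the libraries, the wrong-label test and the pool-age ratio were set before; the intervals that leave the last 2 of these undecided were added after their values were seen.

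Reads outside the gene counts were highest in dorsal closure replicate 2, where 25% of the reads were assigned to no gene and 10.7% aligned to more than 1 place. They lie outside the gene counts on which the stage comparisons rest, and their origin was not examined.

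With stage in the model, 1445 genes were higher and 1509 lower in replicate 2 than in replicate 1. Of 100 drawn splits of the libraries into 5 and 5 (126 exist), 1 gave as many genes, the real one (2911 in the faster fit used for the splits), against at most 971 in the others. This number came from 2 splits that each parted the libraries of 3 stages. With stage in the model, splits that differ only in where whole stages lie give the same fit. The drawn splits therefore repeat some comparisons, and those that part fewer stages rest on fewer pairs of libraries. Of the 11 drawn splits that part all 5 stages, the highest other gave 0, and the 16 such splits are too few for a share under 0.05. Over all 11286 tested genes, 733 (6.49%) had their 5 libraries of one number all above the 5 of the other, where chance gives 0.79%. The nearer comparison is with the other 15 splits that part all 5 stages, which separated 0 to 58 genes (median 4).

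Sequencing depth as the whole cause of the difference between numbers is argued against by an r of 0.49 across genes. It relates the difference at syncytial blastoderm, where replicate 2 is deeper, to the mean difference of the other 4 stages, where replicate 1 is deeper. Developmental age is argued against for most of the 733 separated genes, against 58 in the highest other split, if pools of different age sample 1 time course. For the 2268 called genes that overlap it stays open: their difference correlated with the change between neighbouring stages at r = -0.07, 0.19 and 0.52 at cellular blastoderm, gastrula and germ band extension (an earlier form of the test, whose change ended in a replicate 1 library and so carried the number difference itself, gave -0.32, -0.41 and 0.19). Library batch cannot be told apart from the number, with replicate 2 higher in the percent of reads aligned to more than 1 place in 5 of the 5 stages, in the percent assigned to no gene in 4 and in the percent ambiguous in 3, and apart from age no biological explanation was tested.

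The germ band extension libraries stand apart, at 0.382 and 0.576 of the way from syncytial blastoderm to dorsal closure. This scale is set by each series' own end libraries, so the positions also carry differences between those. The dorsal closure libraries were less alike across genes (r = 0.85) than the germ band extension ones (r = 0.895). Replicate 2 minus replicate 1 differences at germ band extension correlated with those at gastrula and dorsal closure at r = 0.608 and 0.571. Part of the gap was thus shared with other stages. Embryos like those of the dorsal closure pools, mixed into germ band extension replicate 2, are argued against as the source of most of the difference between the germ band extension libraries. In germ band extension replicate 2, the 82 genes that were below 1 CPM in each earlier library and in germ band extension replicate 1, and at 100 CPM or more in both dorsal closure libraries, stood at a median of 0.391% (90th percentile 5.37%) of their level in the lower dorsal closure library. The dorsal closure libraries differed in these genes by a median of 0.77 on the log2 scale (90th percentile 2.05). The 1372 genes 4-fold or more higher in germ band extension replicate 2 than in replicate 1 would need a median share of 31% (quartiles 7.35% and 84.7%) of their level in the higher dorsal closure library, and a 4-fold fall by dilution, for the 1247 genes that were lower, 75%. For the 280 higher genes that would need under 5.37%, and for embryos of an age between the stages, mixing stays open. A wrong label, with replicate 1 a pool of gastrula age, was not decided: the 1357 genes that rose 4-fold or more in replicate 2 had a median log2 ratio of 0.83 in replicate 1, but the share higher there, 76.9% (95% Wilson interval 74.6% to 79.1%, for genes taken as independent), was not clear of the 75% set beforehand, and the 615 genes that fell 4-fold or more in replicate 2 (median -2.57) had a median of -0.17 in replicate 1, with 60.8% lower there. Pools of different age within the stage stay open too. Late genes chosen in the other series had risen 2.02 times as far in replicate 2 as in replicate 1. The median rises were 0.84 and 0.42 on the log2 scale, over different sets of 3416 and 3079 genes. Over 2000 resamples of the genes, the interval of 1.69 to 2.49 spans the 2 set beforehand. This interval takes genes as independent and does not measure the spread between pools.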

How the results depend on the processing

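Alternatives that combine the replicate block with another choice, and the block for the peak counts, were chosen after seeing the data. Pairs of numbers are rises and falls, and the steps are named by their later stage. The 2-fold minimum changed no count, since each called gene already passed it, and the other counts not given here stayed within 1.5 times. The gene lists were not run, because no identifier matched a name.

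The replicate block gave 494 and 410 at cellular blastoderm, 437 and 317 at gastrula, 0 and 0 at germ band extension, 2274 and 2265 at dorsal closure and 3103 falls over the whole series, with 7590 genes over all stages. Its peak counts were 1820, 820, 1215 and 570 for the stages before dorsal closure. The numbers pair the samples by the check on their differences, and of the genes at or above 10 CPM in all libraries it called 2330 over all stages, against 800. Other counts of calls given with the block moved by less than 1.5 times. DESeq2's size factors gave 1059 falls over the whole series. Total counts alone gave 100 falls at cellular blastoderm, 1453 genes highest at syncytial blastoderm and 254 at gastrula. Without a filter 57 and 17 genes were called at gastrula, and the stricter filter gave 313 genes highest at gastrula. DESeq2 gave 567 and 447 at cellular blastoderm, 560 and 342 at gastrula, 170 and 4 at germ band extension and 2236 rises at dorsal closure. limma-voom gave 97 falls at cellular blastoderm and 2202 rises at dorsal closure. With only the libraries of the 2 stages there were 118 rises at cellular blastoderm, 421 and 22 at dorsal closure and 909 falls over the whole series. The cause of these shifts was not tested, except that the fit of 2 stages has fewer libraries and the filters change the genes tested.

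The block with DESeq2's size factors gave 484 and 404 at cellular blastoderm, 444 and 277 at gastrula, 2742 and 1576 at dorsal closure and 7302 over all stages. The block with total counts gave 428 and 747, 401 and 432, and 2331 and 2161 at these steps, 3360 and 3806 over the whole series and 7707 over all stages. DESeq2 with the block gave 1072 and 901 at cellular blastoderm, 942 and 722 at gastrula, 326 calls at germ band extension of which 24 were falls, 2881 and 1957 at dorsal closure and 7829 over all stages. limma-voom with the block gave 531 and 670, 579 and 434, and 3137 and 2638 at cellular blastoderm, gastrula and dorsal closure, 3265 falls over the whole series and 8238 over all stages. The block without germ band extension replicate 1 gave 463 and 529, 484 and 481, and 386 and 24 at the first 3 steps, 2657 falls over the whole series and 7204 over all stages. The block without germ band extension replicate 2 gave 456 and 530, 477 and 480, 1 rise at germ band extension, 2120 and 1563 at dorsal closure, 2667 falls over the whole series and 7096 over all stages.

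Leaving out each library in turn gave, from lowest to highest, 75 to 271 rises and 0 to 83 falls at cellular blastoderm, 0 rises and 0 to 2 falls at gastrula, 0 to 38 rises and 0 falls at germ band extension, and 182 to 1006 rises and 91 to 704 falls at dorsal closure. Over the whole series it gave 1095 to 3037 rises and 763 to 1552 falls, and over all stages 2861 to 4486 genes. The peak counts ran from 468 to 897 at syncytial blastoderm, 183 to 310 at cellular blastoderm, 176 to 374 at gastrula, 195 to 413 at germ band extension and 1422 to 2730 at dorsal closure. For single identifiers, 251 of the values kept their direction and side of the threshold, 35 passed it only under the alternative and 14 no longer passed it. In direction 0 reversed, but the identifiers were chosen for the largest changes, with the same direction in all pairs of libraries. That choice left little room for a reversal. The 35 could come only from the gastrula identifiers, which did not pass without the block. Depth limits the syncytial blastoderm most, where a count of 3 in replicate 1 stands for 0.14 CPM.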

Other observations

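The groups of this part were defined after the data were seen. A set of 18 genes was high through the middle of the series and lower at both ends. The ends were judged relative to the middle, so some genes were not low there (MDOA011028 was at 88.85 CPM in dorsal closure replicate 2). Each stood at or above 10 CPM in all 6 libraries from cellular blastoderm to germ band extension, and below 0.25 of its lowest middle level in every library of syncytial blastoderm and dorsal closure. Another 13 genes did the opposite: they were high at syncytial blastoderm and dorsal closure, and each middle library stood below 0.25 of both end means.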
